A study of Mus musculus with 24 samples.

How the data were processed

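RNA from quadriceps muscle of 2 mouse strains was measured on Affymetrix Mouse 430 2.0 arrays. BL10 is the control strain, and mdx carries a nonsense mutation in Dmd, the dystrophin gene. There were 24 arrays in 8 groups of 3: each strain at 5 days, 2 weeks, 3 weeks and 6 weeks. Groups were taken from the sample titles, and every array stayed in the group its title names. The deposited values are intensity on a linear scale, summarised per probe set by the authors with PLIER. The labels give no PLIER version and do not state its background or scaling settings. Between 2.52% and 5.82% of an array's values lay below 0. The deposited table holds 45101 probe sets, of which 64 are array controls, and no detection calls. The arrays' log2 medians differed by up to 0.21.

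Because that difference exceeded 0.1, arrays were quantile normalized. Values below 0 were set to 0, 16 was added, and log2 was taken, so that the lowest possible log2 value is 4. The added 16 compresses changes of dim genes. Of 45037 probe sets analysed, 34945 carry 1 symbol, 932 carry several and 9160 carry none. Symbols came from the platform's probe set table and were checked against a mouse gene table of assembly GRCm38.p6, used for names alone. No coordinates are given, because the files name no genome build. Each of the 18193 symbols was represented by its probe set of highest mean, and was tested if that probe set lay above the 40th percentile of its own array on at least 3 arrays. This left 15000 genes. The number of arrays limits the precision: the median standard error of an mdx minus BL10 difference was 0.225 on the log2 scale.

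One limma model (version 3.58.1, R 4.3.3) with a mean for each of the 8 groups was fitted to all 24 arrays, with 16 residual degrees of freedom and 5.15 prior degrees of freedom, an intensity trend, and two-sided moderated tests. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were mdx against BL10 at each of 4 ages, the difference of that effect between neighbouring ages, a moderated F-test of the difference over the 4 ages, and 6 weeks against 5 days in each strain. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p below 0.1, so calls rest on the spread that limma pools over genes and groups. Of 37 gene lists, 36 had at least 5 members tested. They were compared with all other genes by limma's camera with a preset correlation of 0.01, two-sided, adjusted over the lists. Camera was repeated with a correlation estimated from the data.

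The tests, the lists, the rule for naming genes and the other settings were fixed before the data were examined. The rule names Dmd and Utrn, then the 10 highest and 10 lowest changes among called genes whose 3 arrays all lay beyond the other 3, and up to 4 called members of each list. For the F-test it names the 10 genes with the widest spread of the 4 log2 differences, and for the change with age the 5 highest and 5 lowest in each strain. Not every gene so named is printed. The other settings were values as deposited, median centring, added constants of 1 and 64, no filter, a filter at the 60th percentile, all probe sets, the mean of a gene's probe sets, no intensity trend, array weights, each age fitted alone, a block for the replicate number, stricter calls, other set tests and leaving out each array. Leave-outs of groups of arrays whose Dmd values contradict the label were chosen after seeing the data.

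The fit was tested on 10 simulated draws of the 3-week comparison over 15000 genes. Of 100 genes shifted by 1 on the log2 scale, 54% to 68% were recovered per draw. Of 100 shifted by 2, 88% to 99% were recovered. Between 5 and 15 unshifted genes were called per draw, and the shifted list was called in 10 of 10 draws. The simulated noise was independent between genes and equal over arrays, whereas the array weights ran from 0.36 to 4.38. The draws therefore do not show how many false calls correlated genes or uneven arrays give. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.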

Results

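Gene expression was measured in quadriceps of BL10 control mice and of dystrophin-deficient mdx mice at 5 days, 2 weeks, 3 weeks and 6 weeks, an age range in which the muscle of mdx mice goes from no visible injury to repeated degeneration and repair. Each of the 8 groups had 3 arrays. The median deposited intensity per array ran from 43.82 to 53.11. Values below are log2(intensity + 16) after quantile normalization, and differences are mdx minus BL10 by array label, given with the standard error of the limma fit (n = 3 per group).

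The gene that carries the mutation was examined first in every array. The brightest Dmd probe set, 1448665_at, read 9.87, 10.02 and 10.02 in the arrays labelled BL10 at 5 days, and 8.29, 8.06 and 8.48 in those labelled mdx. At 2 weeks it read 9.18, 10.03 and 10.08 in arrays labelled BL10 and 7.73, 8.33 and 10.31 in arrays labelled mdx. At 3 weeks it read 8.88, 8.02 and 10.13 in arrays labelled BL10, and 7.94, 7.64 and 8.25 in arrays labelled mdx. At 6 weeks it read 9.83, 10.25 and 10.10 in arrays labelled BL10 and 9.84, 9.99 and 10.04 in arrays labelled mdx, so the groups overlapped. The array labelled mdx at 2 weeks, replicate 3, therefore lay above every array labelled BL10 at its age, and the array labelled BL10 at 3 weeks, replicate 2, lay within the range of arrays labelled mdx. A further Dmd probe set, 1417307_at, and Erdr1 probe set 1452406_x_at also separated the strains at 5 days by over 1 on the log2 scale, and were chosen for that after their values were seen. The dimmer Dmd probe sets and the other Erdr1 probe set did not. Relative to the midpoints of the 5-day groups (9.12, 8.57 and 8.17), 5 arrays had all 3 probe sets on the side of the other strain: those 2 arrays and the 3 labelled mdx at 6 weeks. In 2 more arrays, BL10 at 2 weeks replicate 1 and BL10 at 3 weeks replicate 1, 1 or 2 of the 3 lay on the other side. None of 45037 probe sets separated all arrays labelled mdx from all labelled BL10 (0 of them). The Dmd difference was -1.69 ± 0.47 at 5 days (adjusted p 0.0746), -0.98 ± 0.47 at 2 weeks (adjusted p 0.365), -1.07 ± 0.47 at 3 weeks (adjusted p 0.161) and -0.11 ± 0.47 at 6 weeks (adjusted p 1). With the 2 arrays above left out, a choice made after seeing the data, it was -1.69 ± 0.28 (adjusted p 0.003), -1.74 ± 0.31 (adjusted p 0.0724), -1.56 ± 0.31 (adjusted p 0.00404) and -0.11 ± 0.28 (adjusted p 1). The 2 arrays left out were picked by their Dmd values, so the larger differences at 2 and 3 weeks and the smaller errors follow from the choice. Those adjusted p-values do not count as tests of Dmd. With all arrays in, the error of 0.47 is pooled over the groups and is the same at each age. The standard deviations of this probe set at 5 days were 0.08 in BL10 and 0.21 in mdx. They were 1.35 in mdx at 2 weeks and 1.06 in BL10 at 3 weeks, the groups that hold the 2 arrays. The adjusted p of 0.0746 at 5 days therefore rests in part on the spread at other ages. Utrn, which encodes the related protein utrophin, was not called at any of the 4 ages, with differences of 0.51, -0.24, 0.59 and 0.06.

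**Figure D1:**
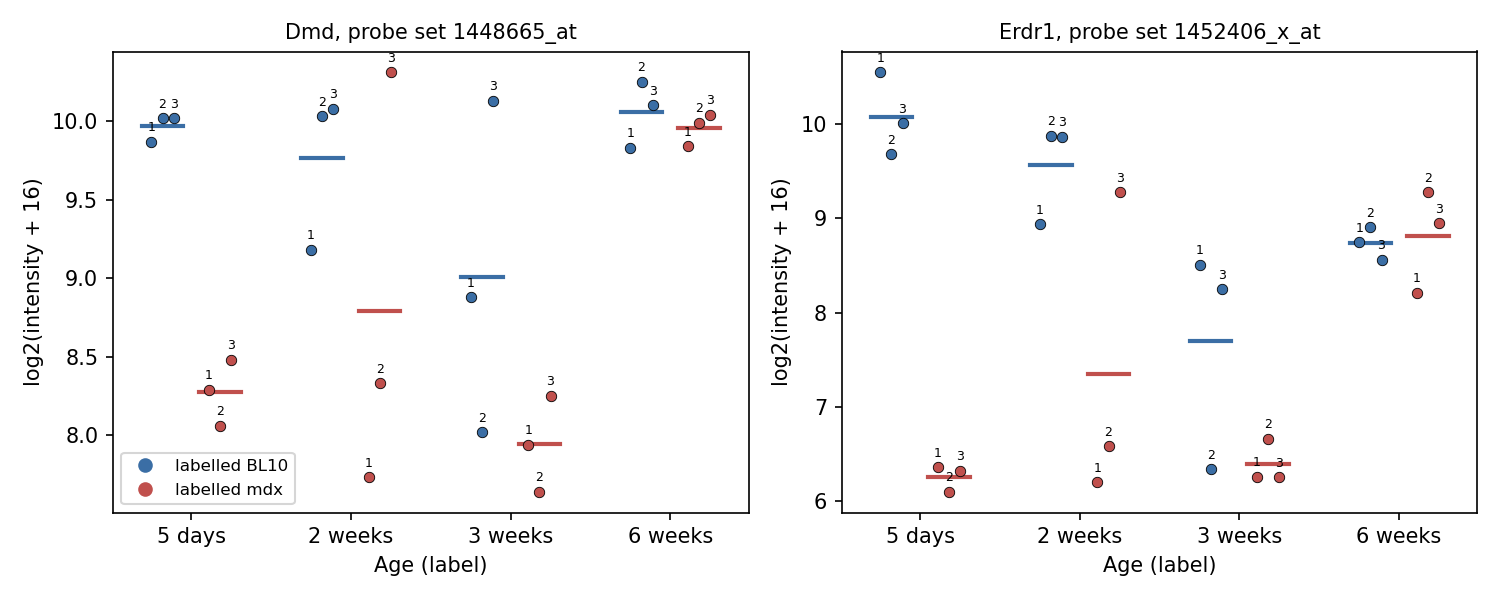
Dmd and Erdr1 in each array, as log2(intensity + 16), against the labelled age, with points for arrays (replicate number beside each) and bars for group means (n = 3). Replicate 3 labelled mdx at 2 weeks reads 10.31 for Dmd, replicate 2 labelled BL10 at 3 weeks reads 8.02, and the groups at 6 weeks overlap.

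Whether the strains differ before the muscle is injured was addressed at 5 days. Fast muscle fibre genes were lower in mdx. Myh4 (1427026_at) fell by 2.15 ± 0.26 (adjusted p 0.000167), and Myh2, Pvalb and Myoz3 by 2.23, 1.52 and 1.61. Rpl3l fell by 2.09 and Aqp4 (1434449_at), a water channel of the muscle membrane, by 2.42 ± 0.32 (adjusted p 0.000472). Of 18 fast fibre genes 5 were called lower, the list's median difference was -0.24, and it was the 1 list at this age that stayed past the threshold with an estimated correlation (adjusted p 8.63e-07 with the preset and 0.0367 with the estimated correlation). Higher in mdx were Lcn2 (1427747_a_at, 4.39 ± 0.78, adjusted p 0.00578), the metallothioneins Mt1 and Mt2 (3.40 and 3.21), Hsd11b1 (2.49), Egfbp2 (2.54) and Adh1 (2.26). The endothelial markers had a median of -0.80 (adjusted p 1.45e-09), with 1 of 15 called over all genes and 14 adjusted over the list alone. The atrophy and autophagy genes had a median of 0.76 (adjusted p 4.03e-09), with 0 of 18 called over all genes and 11 adjusted over the list alone. Both lost the call with an estimated correlation (adjusted p 0.277 for each). The mitochondrial respiratory chain list (median -0.15), calcium handling (-0.32), glycolysis (-0.21), erythroid (-0.29), mast cell and eosinophil (0.79) and oxidative stress (0.15) lists were also called with the preset correlation alone. In all, 216 genes were called, 78 higher and 138 lower, and 136 of them changed at least 2-fold. Groups did not overlap for 23.2% of genes, where chance gives 10%. The count depended on single arrays: it was 45, 60 and 71 without BL10 replicates 1, 2 and 3, 706 without mdx replicate 1, and 73 without mdx replicate 2. BL10 replicate 1 reads as female, with Xist at 11.65 and the Y-linked Eif2s3y, Kdm5d and Uty at 4, 4.03 and 4.07, at or near the floor, while BL10 replicates 2 and 3 read as male (Eif2s3y 9.14 and 9.34). Sex is therefore mixed within this group, in the comparison at 5 days and in that of BL10 with age. Fitted to this age alone, the count was 12, of which 9 were among the 216.

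At 2 weeks, just before the age at which injury becomes widespread, limma called 0 genes, while 2084 had an unadjusted p under 0.05 and 13.7% of genes did not overlap (10% by chance). The count became 922 without BL10 replicate 3 of this age, 1 without mdx replicate 3, and 3 and 1 without mdx at 5 days replicates 2 and 3. It was 537 with array weights and 9 over all probe sets. Without the 2 arrays whose Dmd reads as the other strain it was 2, Erdr1 (-3.17 ± 0.31, adjusted p 5.05e-05) and Tmem181a (-1.49 ± 0.24, adjusted p 0.0452), both named after their values were seen. Erdr1 was among the probe sets that marked these arrays, so its p-value follows from the choice and does not count as a test. Of 36 lists 6 were called with the preset correlation and 0 with an estimated one. The 6 became 1 without BL10 replicate 2 of this age, and 10 without BL10 replicate 1 or without mdx replicate 3. Among the 6, glycolysis (median 0.39, adjusted p 2.26e-08), the respiratory chain (0.11), atrophy and autophagy (0.32) and lysosome (0.20) were higher, and cell cycle (-0.38) and myogenic regulators (-0.41) lower. With values as deposited these medians were, in the same order, 0.59, 0.32, 0.49, 0.34, -0.31 and -0.30, so their size rests on the scaling. Without the 2 arrays 10 lists were called with the preset correlation, and cell cycle and myogenic regulators were not among them. Newly called, all higher, were the macrophage (median 0.41), neutrophil (1.12), slow fibre (0.62), fatty acid oxidation (0.54), extracellular matrix (0.25) and oxidative stress (0.30) lists. No member of these lists was called singly. Of the mdx arrays left, replicate 1 had macrophage, neutrophil and slow fibre means of 7.81, 8.54 and 11.27, above every BL10 array of this age. Replicate 2, at 7.18, 6.93 and 10.60, lay inside the BL10 range for each. The rise of those lists therefore rests on 1 array.

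At 3 weeks, the age at which degeneration and repair are under way in mdx muscle, most macrophage markers and interferon response genes, and some genes of developing muscle, were higher in mdx. Mpeg1 (1427076_at) rose by 4.21 ± 0.59 (adjusted p 0.000931), Ptprc (1422124_a_at) by 2.96 ± 0.41 (adjusted p 0.000931), Ctss by 3.20, Lgals3 by 3.39 and Gpnmb by 3.12. Of 29 macrophage markers 22 were called higher over all genes and 25 adjusted over the list alone, with a median of 1.42. Their mean was 7.80, 8.84 and 9.13 in the arrays labelled mdx and 7.16, 7.11 and 6.71 in those labelled BL10, so mdx replicates 2 and 3 carry most of the rise. Replicate 1 labelled mdx correlated at 0.988 with mdx at 2 weeks replicate 1, whose mean was 7.81. Of 25 interferon genes 14 were called higher, with a median of 1.37 and Ifit1, Oasl2 and Usp18 at 2.88, 2.93 and 2.14. Chemokines included Ccl2 (2.96), Ccl12 (2.90) and Cxcl10 (2.19). Of 14 developmental muscle genes 5 were called higher, and the list (median 0.47) was called with the preset correlation and not with an estimated one (adjusted p 0.00414 and 0.386). Its median was 1.14, with 7 genes called higher, without the 2 arrays whose Dmd reads as the other strain, so its size rests on single arrays. Among the 5, Myh3 (1427115_at), the embryonic myosin, rose by 2.77 ± 0.66 (adjusted p 0.0144), Tnnt2 by 2.53 and Ankrd1 by 1.93. Chrng, of the fetal acetylcholine receptor, was at or below 0 in 2 of the 3 arrays labelled BL10. Mymx, needed for fusion of myoblasts, rose by 1.80, and the repair genes Myof and Anxa1 by 1.41 and 1.27. Timp1 rose by 2.97 and Thbs1 by 1.52. Of 32 respiratory chain genes 2 were called lower, Sdhb (-0.44) and Sdhc (-0.79). That list had a median of -0.21 and was called with the preset correlation and not with an estimated one (adjusted p 5.14e-06 and 0.416). Stim1 (-0.67) and Orai1 (-1.07), which carry store-operated calcium entry, were also lower. Called with the preset correlation were 16 lists, with an adjusted p of 6.61e-20 for macrophages and 7.38e-14 for interferon. With an estimated correlation 0 were called (0.137 and 0.208 for those lists). In all, 1216 genes were called, 730 higher and 486 lower, and 442 changed at least 2-fold. Groups did not overlap for 23.3% of genes (10% by chance). Of the called genes 60% were higher after quantile normalization, 82% with values as deposited and 83.1% with median centring, so the share of lower genes rests on the scaling. Fitted to the 6 arrays of this age alone, limma called 0 genes, while 3834 had an unadjusted p under 0.05 in the fit to all arrays. A sign of RNA quality also differed between these groups: the log2 difference of the 3' and 5' Gapdh control probe sets was 0.75, 0.37 and -0.16 in the arrays labelled mdx and -0.21, -0.22 and -0.18 in those labelled BL10. The same difference for the actin control was -0.20, -0.10 and -0.05 against -0.16, -0.20 and -0.20, and overlapped. The count was 520, 2105 and 486 without BL10 replicates 1, 2 and 3, and 673 and 456 without mdx replicates 2 and 3. Without the 2 arrays whose Dmd reads as the other strain it was 2284, of which 1110 were among the 1216. Genes called at 5 days and at 3 weeks in the same direction were 4 higher and 7 lower, where independence gives 3.8 and 4.47.

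**Figure D2:**
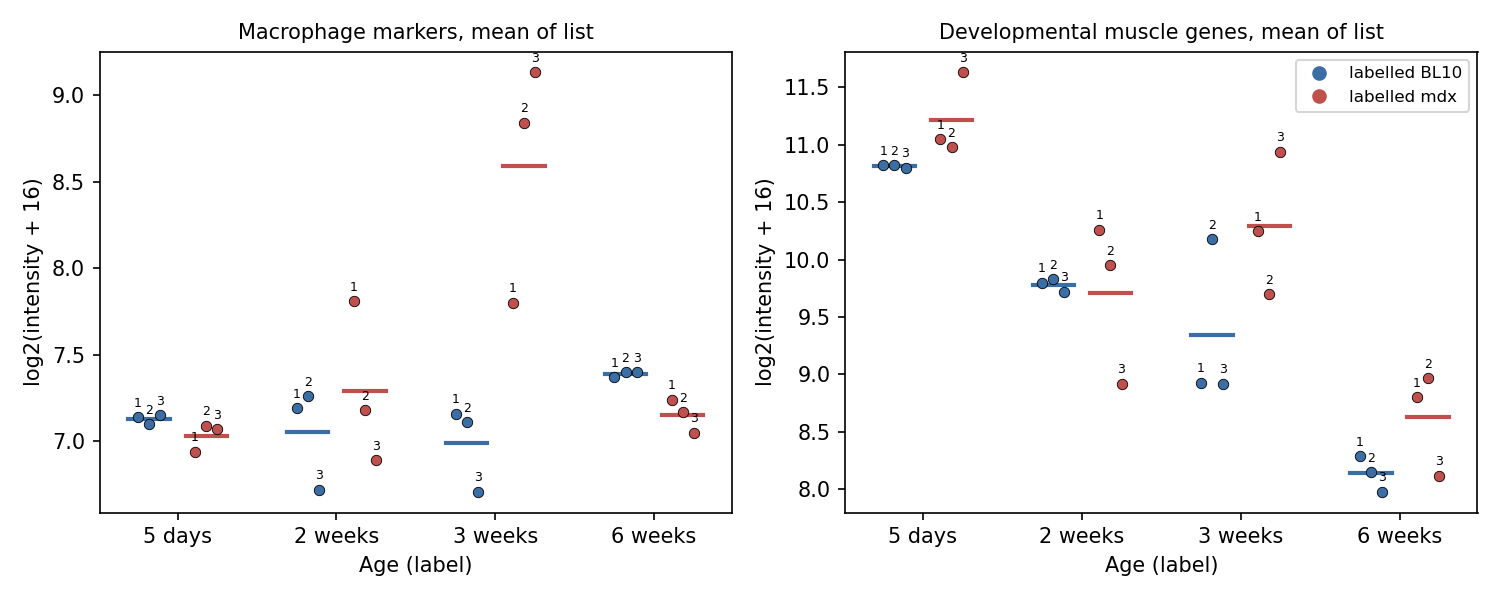
Mean of the macrophage markers and of the developmental muscle genes in each array, as log2(intensity + 16), against the labelled age, with points for arrays (replicate number beside each) and bars for group means (n = 3). The developmental mean of the array labelled BL10 at 3 weeks, replicate 2, is 10.18, against 8.93 and 8.92 in the other arrays of its group.

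At 6 weeks the arrays labelled mdx did not differ from BL10 in Dmd, so the comparison is between labelled groups. The called genes were mostly lower in the arrays labelled mdx. Fmod (1456084_x_at) fell by 5.19 ± 0.81 (adjusted p 0.00634) and Kera (1418063_at) by 5.04 ± 0.80 (adjusted p 0.00634). Tnmd (1417979_at) fell by 4.13 ± 0.60 (adjusted p 0.00547). Chad was at or below 0 in 2 of the 3 arrays labelled mdx, and Kera came near the floor of 4 (lowest 4.36), so its difference is compressed. Ptx4, Zic1, Itgbl1, Mgp, C1qtnf7 and the clock gene Ciart were also lower, and Six3 was higher by 1.14. In all 12 genes were called, 1 higher and 11 lower, 529 genes had an unadjusted p under 0.05, and 15.5% did not overlap (10% by chance). The count was 7 and 6 without mdx replicates 1 and 2 of this age, and rose to 22, 19 and 21 without mdx at 2 weeks replicate 2, BL10 at 3 weeks replicate 2 and mdx at 3 weeks replicate 1. Fitted to this age alone, 104 genes were called, 9 of them among the 12. Extracellular matrix (median -0.38, adjusted p 3.02e-13), matrix remodelling (-0.28), fibro-adipogenic progenitor (-0.36), complement (-0.37), circadian (-0.41) and macrophage (-0.24) lists were lower. Slow fibre genes (0.89, adjusted p 9.82e-13), developmental muscle (0.28), cell cycle (0.23), Schwann cell (0.34) and neuromuscular junction (0.19) lists were higher. None of these 11 lists was called with an estimated correlation (0 of them). The mean of the slow fibre genes was 10.43, 10.70 and 8.93 in the arrays labelled mdx and 9.05, 7.77 and 8.14 in those labelled BL10, so these groups overlapped.

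**Figure D3:**
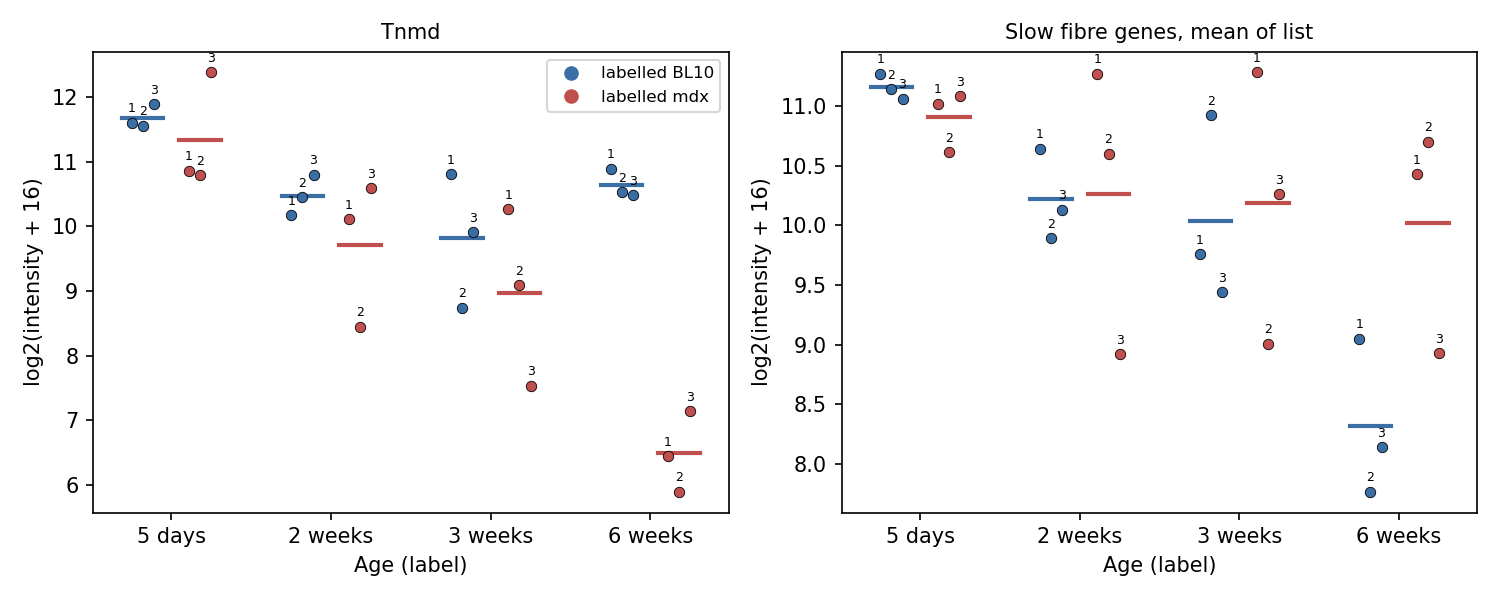
Tnmd and the mean of the slow fibre genes in each array, as log2(intensity + 16), against the labelled age, with points for arrays (replicate number beside each) and bars for group means (n = 3). At 6 weeks the slow fibre mean of replicate 3 labelled mdx is 8.93, inside the BL10 range of 7.77 to 9.05.

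Whether the effect of the strain changed with age was tested as a difference of differences. Over the 4 ages the difference between the labelled groups varied for 236 genes (2934 at an unadjusted p under 0.05). Without the 3 arrays labelled mdx at 6 weeks, whose Dmd reads as BL10, 52 genes varied over the ages left, all 52 among the 236. Mpeg1 differed by -0.34 at 5 days, 1.35 at 2 weeks, 4.21 at 3 weeks and -0.74 at 6 weeks (adjusted p 0.0168). Tnc, a matrix protein of injured tissue and tendon, differed by 0.72, 0.62, 1.71 and -2.86 (adjusted p 0.0229), and Ankrd1 by 1.21, 1.20, 1.93 and -2.43 (adjusted p 0.022). Between 5 days and 2 weeks 28 genes differed, between 2 and 3 weeks 20, and between 3 and 6 weeks 157, of which 129 moved down. For macrophage markers the mdx minus BL10 difference fell by a median of 1.67 between 3 and 6 weeks (adjusted p 1.76e-20, and 0.0945 with an estimated correlation). For 10 of the 29 that fall of the difference was called. Part of it is a rise in BL10, whose means were 7.16, 7.11 and 6.71 at 3 weeks and 7.37, 7.40 and 7.40 at 6 weeks. It also rests on the 6-week arrays labelled mdx, whose Dmd reads as BL10. For fast fibre genes the difference moved up by a median of 0.56 between 5 days and 2 weeks (adjusted p 1.85e-06, and 0.0456 with an estimated correlation). These counts depended on single arrays, with 17 to 1055 genes over the 4 ages, 4 to 490, 0 to 1046 and 21 to 335 between neighbouring ages when 1 array was left out. The lowest of these came without BL10 at 3 weeks replicate 3, BL10 at 2 weeks replicate 1, BL10 at 5 days replicate 1 (among others) and BL10 at 3 weeks replicate 3 or mdx at 6 weeks replicate 3. The highest came without BL10 at 2 weeks replicate 3 for all but the last, and without mdx at 3 weeks replicate 1 for the last.

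**Figure D4:**
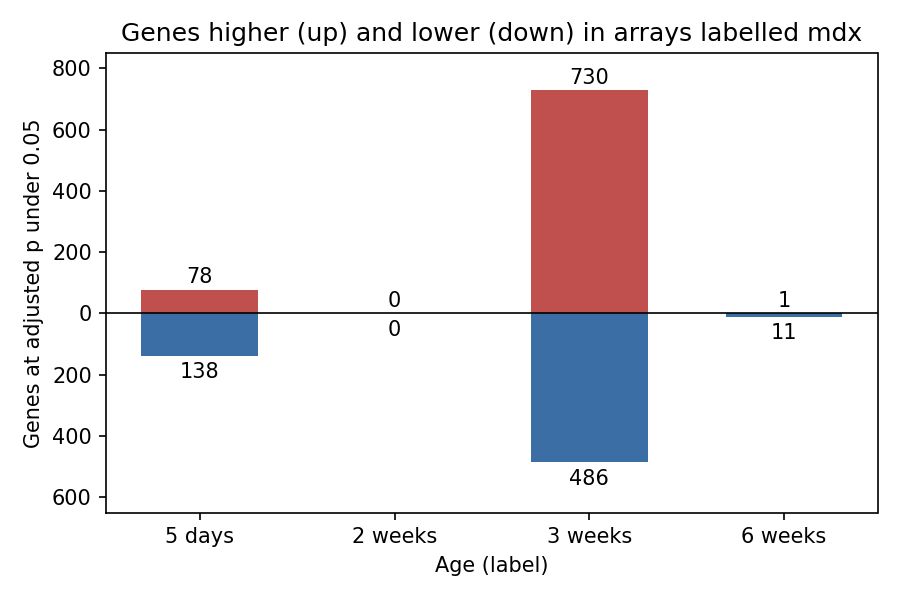
Genes called at an adjusted p under 0.05 at each labelled age, with those higher in arrays labelled mdx drawn upward and those lower drawn downward. The counts are 78 and 138 at 5 days, 0 and 0 at 2 weeks, 730 and 486 at 3 weeks, and 1 and 11 at 6 weeks. All rest on a spread shared by the groups, although the groups varied unequally.

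**Figure D5:**
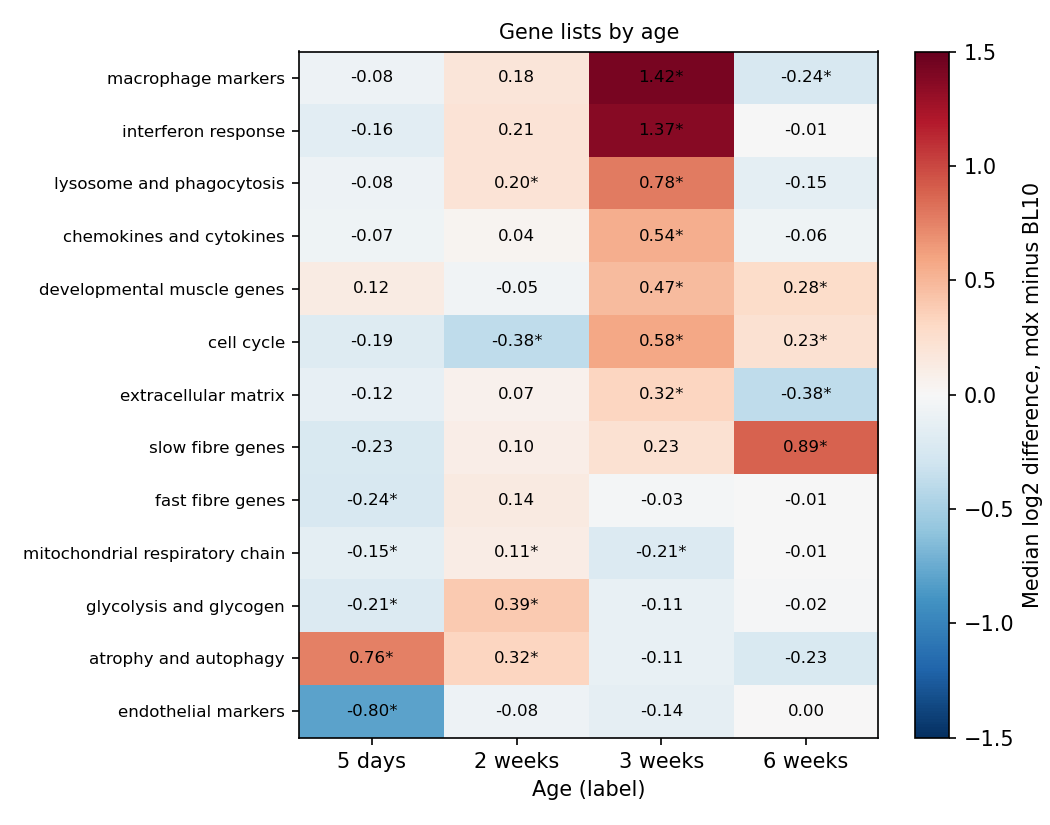
Median log2 difference, mdx minus BL10, of selected gene lists at the 4 labelled ages, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. Macrophage markers read 1.42 at 3 weeks and -0.24 at 6 weeks, and without quantile normalization the sign flips for lysosome at 5 days (median centred), developmental and endothelial at 2 weeks, and fast fibre, atrophy and endothelial at 3 weeks, none of them called.

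Growth from 5 days to 6 weeks changed more genes than the strain did at any of the 4 ages. In BL10 5699 genes were called, 3414 higher and 2285 lower, and in mdx 6171, 3658 higher and 2513 lower, although the Dmd level differs between these mdx groups. Shared in direction were 2521 higher and 1593 lower, where independence gives 833 and 383. Of 14 developmental muscle genes 10 were called lower and 2 higher in BL10, and 8 lower and 2 higher in mdx. Of 12 slow fibre genes 9 were called lower in BL10, against 3 lower and 2 higher in mdx. Among all genes, those that fell in BL10 included Dlk1 (1449939_s_at) by 7.40 ± 0.71 (adjusted p 3.16e-07), Sln by 6.55, Myh3 by 6.05, Tnni1 by 5.63, Igf2 by 5.30 and Myh8 by 4.62. Cyp2e1 rose by 6.48, Mylk2 by 2.47 and Pvalb by 1.86. Mup3 was at or below 0 in the 3 arrays of either strain at 5 days and read 10.17 in BL10 and 9.10 in mdx at 6 weeks. Of 31 cell cycle genes 25 were called lower in BL10 and 12 in mdx, and of 19 glycolysis genes 15 and 18 were called higher. Developmental muscle genes had medians of -3.32 in BL10 and -3.14 in mdx. With an estimated correlation 0 lists were called in either strain. Dmd rose by 1.68 ± 0.47 in the arrays labelled mdx (adjusted p 0.00773). The log2 difference of the 3' and 5' Gapdh control probe sets also moved with age, from between -0.16 and -0.09 in the 6 arrays at 5 days to between 0.19 and 0.60 in the 6 arrays at 6 weeks. That of the actin control ran from -0.29 to -0.08 and from -0.31 to -0.22, and overlapped. Each age was a group of its own, so age, RNA quality and any run batch cannot be told apart.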

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

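The tests of exchanged labels, degraded RNA, missing mutation and scaling were chosen after the values had been seen. The tendon marker list and the counts over other splits of the arrays were set before their own values were seen. The list takes up a fall of tendon genes found in these arrays, so it is a follow-up and not an independent test.

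The difference between arrays labelled mdx and BL10 varied over the 4 ages for 236 genes, by a test of the difference itself. Without the 3 arrays labelled mdx at 6 weeks, which may not carry the mutation, it varied for 52 genes over the ages left, a fit with fewer arrays and an age fewer, so the counts are not of the same form. Leaving out the single array BL10 at 3 weeks replicate 3 gave 17. The widest spreads of the 4 log2 differences were 5.85 for Prg4, 4.95 for Mpeg1, 4.82 for Fmod, 4.57 for Tnc, 4.36 for Ankrd1, 3.79 for Tnmd, 3.73 for Timp1, 3.68 for Plek, 3.66 for Mss51 and 3.65 for Clec7a. In 1 of 100 splits (the real one) as many genes differed, with 70 as the highest other. The splits exchange strain labels within each age, so they stand for no strain difference at any age. They do not stand for a difference that is equal at all ages, so they cannot exclude chance for a change with age. Between 5 days and 2 weeks 28 genes differed, a count reached by 4 of 100 splits (highest other 69). Between 3 and 6 weeks 157 differed, reached by 2 of 100 (highest other 179). Each share taken alone is under 0.05, but these splits have the same limit and do not test a change with age. Other splits gave more genes than the labels in both, and the shares are not adjusted for the 4 tests. The 28 became 4 without BL10 at 2 weeks replicate 1, and the 157 became 21 without BL10 at 3 weeks replicate 3. Between 2 and 3 weeks 20 genes differed, a count that 12 of 100 splits reached, so chance is not excluded. The highest other split gave 1824 genes, which points to a structure of the 2-week and 3-week arrays other than their labels.

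Probe sets without a single symbol, which the gene tests leave out, also passed the threshold: 48 at 5 days, 1 at 2 weeks, 297 at 3 weeks and 1 at 6 weeks, of 5988 tested.

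The first pattern is the pair of arrays labelled mdx at 2 weeks replicate 3 and BL10 at 3 weeks replicate 2. Degraded RNA is argued against in both. In the second, the log2 difference of the 3' and 5' Gapdh control probe sets was -0.22, against -0.21 and -0.18 in the other arrays of its group. In the first it was -0.21, against -0.19 and -0.10 in the others labelled mdx at 2 weeks. The Dmd reading of 10.31 in the first is the pattern itself and does not test degradation. What stays open is that the 2 arrays carry each other's labels. The Dmd and Erdr1 readings raised the idea and cannot test it. An index of age could have come out otherwise. In 2 of 2 arrays it lay nearer to the age the other label names, by the mean of that age's other arrays of both strains. The index, set to 0 at 5 days and 1 at 6 weeks in BL10, was 0.76 and 0.46 in these arrays, against 0.42 and 0.52 in the others labelled mdx at 2 weeks and 0.77 and 0.81 in the others labelled BL10 at 3 weeks. It does not separate the ages fully, since mdx at 3 weeks read 0.47, 0.76 and 0.58, and it does not test the strain. The 0.46 of the second array could also be that of an mdx array at 3 weeks. For that array the index cannot tell an exchange from a wrong strain label. Across genes, the first array correlated best with BL10 at 3 weeks replicate 3 (0.975). The second correlated best with mdx at 2 weeks replicate 2 (0.978). The closest array need not share the strain, since BL10 at 2 weeks replicate 3 was also closest to mdx at 2 weeks replicate 2 (0.976). An exchange may explain both arrays, as a hypothesis found on these data. A description in the labels also gives 3 weeks for the first array. The arrays were not regrouped.

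The second pattern is that the arrays labelled mdx at 6 weeks have Dmd at the level of BL10. Scaling is argued against as the cause, since the lowest Dmd difference under the 3 scalings was -0.14. What stays open is that the 3 arrays may hold muscle without the mdx mutation. The 9 of 9 values of both Dmd probe sets and Erdr1 on the BL10 side are the pattern itself and do not test this. Escape of mutant Dmd transcripts from decay would leave Erdr1 unexplained, which read 8.21, 9.28 and 8.95 here, against 8.75, 8.91 and 8.56 in BL10 of this age and 6.36, 6.10 and 6.32 in mdx at 5 days. The macrophage markers had a median difference of 1.42 at 3 weeks and of -0.24 at 6 weeks. Their mean at 6 weeks was 7.24, 7.17 and 7.05 in the arrays labelled mdx, all below the 7.37, 7.40 and 7.40 of BL10. Muscle without the mutation, or injury that had passed, could leave no rise, but neither by itself gives a lower level. These markers therefore do not decide between the readings. A missing mutation and a change with age of both genes cannot be told apart, because the arrays hold no reading of the mutation. With either reading, the 12 genes called at 6 weeks compare labelled groups.

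The third pattern is the fall of Fmod, Kera, Chad and Tnmd at 6 weeks. Scaling is argued against, since the difference of each of the 4 moved by 0.13 or less under the other scalings. Chad is at the floor of 4 in 2 of the 3 arrays labelled mdx, so its difference is a bound, while Kera (-5.04, lowest array 4.36), Fmod (-5.19, lowest array 5.95) and Tnmd (-4.13, lowest array 5.90) lie above it. A candidate explanation is less tendon in the pieces labelled mdx. A list of 12 other tendon markers, written before the test, had a median of -1.26 with 12 of 12 below 0, from -3.72 (Comp) to -0.18 (Mkx), and no member was called singly. Of the 12, 4 also belong to other lists, and 4 had a mean above 8, a level chosen after seeing the values, in the arrays labelled mdx. The brightest probe set, that of Thbs4, read 11.68 in BL10 and 10.08 in mdx, and intensities of different probe sets do not rank transcripts. A lower expression by tendon cells, or a difference of the strain, was not tested and stays open. The lower extracellular matrix list at 6 weeks (median -0.38) shares Fmod and other tendon genes, so it is not independent of this pattern.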

How the results depend on the processing

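The 3 settings that leave out several arrays were chosen after seeing the data, and the others were planned. Where no cause is named below, the cause was not tested. For single named genes, 5340 of 5901 values under planned settings kept their direction and side of the threshold, 544 lost the call, 6 gained it and 11 changed sign. Leaving out 1 array kept 9340 of 9957, and leaving out several kept 1004 of 1091. The median difference of all genes moved most at 3 weeks, from -0.018 to 0.087 with values as deposited and 0.081 with median centring, so changes of that size at 3 weeks rest on the scaling. Counts of genes are in the order 5 days, 2, 3 and 6 weeks (216, 0, 1216, 12), then differences from 5 days to 2 weeks, 2 to 3 weeks and 3 to 6 weeks (28, 20, 157), over the 4 ages (236) and age in BL10 and mdx (5699, 6171). Only counts that moved by over 1.5 times are given.

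Values as deposited gave 45, 0 and 289 for the differences, 362 over the 4 ages and 10 lists at 2 weeks (6 before). Median centring gave 0 and 354 for the later differences. For 2 to 3 weeks, an added 1 gave 0, an added 64 gave 51, no filter 0, the mean of probe sets 7 and no intensity trend 0. The filter at the 60th percentile gave 6 at 6 weeks, and 45 and 45 for the earlier differences. All probe sets, with more features tested, gave 390, 9, 2053 and 25 by age, 67 and 243 for the earlier differences, 379 over the 4 ages, and 12486 and 13690 with age. Array weights gave 389, 537, 753 and 295 by age, 236, 379 and 761 for the differences, 1446 over the 4 ages and 9217 for age in BL10. Each age fitted alone, with fewer arrays behind the spread, gave 12, 0 and 104 at 5 days, 3 and 6 weeks. Fewer arrays alone do not account for the rise at 6 weeks. Arrays of a group correlated at 0.972 to 0.986 at 6 weeks and at 0.937 to 0.957 at 3 weeks. A spread shared by all groups is therefore wide for 6 weeks and narrow for 3 weeks. Counts at different ages are not on an equal footing. A stricter call at 2-fold gave 136 and 442 at 5 days and 3 weeks, and 2376 and 2693 with age. An adjusted p under 0.01 gave 61, 281 and 7 at 5 days, 3 and 6 weeks, 4, 0 and 0 for the differences, 6 over the 4 ages, and 3582 and 4099 with age.

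A replicate block within each age gave 2 at 2 weeks, 25 at 6 weeks, 47 and 204 for the earlier differences, and 2435 and 2849 with age, and a block over all ages gave 59 from 2 to 3 weeks. The labels do not say that a number marks a shared litter or day, and the numbers were to be taken as pairs only if every same-numbered pair correlated above 0.1. Of 12 pairs 8 did, and the others were at 0.08, 0.05, -0.15 and -0.25, so they are not. That 10 of 12 mdx arrays were closest to the BL10 array of their number is a hint from the data, not from the design.

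The counts of lists (9, 6, 16 and 11) became 1, 0, 0 and 0 with an estimated correlation, and 1, 0 and 0 with fry at 5 days, 2 and 6 weeks, while fry called 12 at 3 weeks. Without the arrays labelled mdx at 2 weeks replicate 3 and BL10 at 3 weeks replicate 2, counts were 2, 2284 and 22 at 2, 3 and 6 weeks, 18, 0 and 361 for the differences, 405 over the 4 ages and 10 lists at 2 weeks. Without these and replicate 1 of BL10 at 2 and at 3 weeks, they were 406 and 2 at 5 days and 2 weeks, 3, 0 and 314 for the differences, and 14 lists at 2 weeks. Without the 3 arrays labelled mdx at 6 weeks, they were 135 at 5 days, 5 and 0 for the earlier differences and 52 over the ages left.

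Leaving out each array in turn gave 45 to 706 at 5 days, 0 to 922 at 2 weeks, 456 to 2105 at 3 weeks and 6 to 22 at 6 weeks. It gave 4 to 490, 0 to 1046 and 21 to 335 for the differences, 17 to 1055 over the 4 ages, 4307 to 5912 for age in BL10 and 4912 to 6409 in mdx, and 7 to 11, 1 to 10, 14 to 19 and 10 to 15 lists by age. A group left with 2 arrays is assumed to vary like the others. At 2 weeks the count was also 3 and 1 without mdx at 5 days replicates 2 and 3, and 1 without mdx at 2 weeks replicate 3.

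The following changed sign. With the mean of probe sets, Utrn at 2 weeks was 0.058, Mcm3 and Slc4a1 at 3 weeks 0.557 and 0.036, and Dmd at 6 weeks 0.065. With the same setting, Ikbkb, Ndufa10, Ryr1, Srxn1 and Tfrc changed with age in BL10 by -0.225, 0.702, -0.036, -0.366 and -0.547, and Nfe2l2 in mdx by -0.608. Nos1 in BL10 (1.673) became -0.072 with an added 1, -0.064 without the arrays labelled mdx at 6 weeks, and ranged from -0.116 to 1.851 over the fits without 1 array. Mcm3 at 3 weeks (-0.509) ranged from -0.694 to 1.213 over the fits without 1 array and became 1.592 without 4 arrays, and 3 other probe sets of Mcm3 were called the opposite way. Utrn became 0.003 at 2 weeks without 4 arrays, and at 6 weeks ranged from -0.063 to 0.135 over the fits without 1 array. Cd8a in mdx with age ranged from -0.304 to 1.006, the former without mdx at 6 weeks replicate 3. Dim genes are the least certain, since values at the floor of 4 hide any lower signal.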

Other observations

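The hypothesis below on maturation and the counts over other splits were set before the values they test were seen. The remaining values were looked up afterwards.

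If muscle of mdx mice matured later, the genes lower in mdx at 5 days would rise with age in BL10, and the genes higher would fall. From 2 to 6 weeks in BL10, the 138 lower genes had a median change of -0.16, with 40.6% rising, and the 78 higher genes had a median of 0.24, with 64.1% rising, against 0.03 and 52.8% for all genes. Both medians lie on the opposite side from the one a delay needs, which the rule set beforehand counted against a delay. The quartiles, which were not part of that rule, run from -0.58 to 0.29 for the lower genes and from -0.09 to 0.55 for the higher genes. Some genes of either set therefore moved as a delay needs. Of the 9 lists called at 5 days with the preset correlation, 5 were also called from 5 days to 6 weeks in BL10. Fast fibre, glycolysis and respiratory chain genes were lower in mdx (medians -0.24, -0.21 and -0.15) and rose with age (0.37, 0.66 and 0.32), and mast cell markers were higher (0.79) and fell with age (-1.65), as a delay needs. Endothelial markers were lower (-0.80) and fell with age (-0.54), the opposite. The other lists, of atrophy, calcium handling, oxidative stress and erythroid genes, were not called with age. Both comparisons subtract the same BL10 arrays at 5 days, and noise in these moves both differences the same way, against a delay. With an estimated correlation only the fast fibre list kept its call at 5 days (adjusted p 0.0367), and it was not called with age (0.197). By the rule set beforehand, the medians of the called genes count against a delay. The change from 2 to 6 weeks leaves out the time before 2 weeks, and both ranges of quartiles hold rises and falls. That change therefore cannot decide. The lists went both ways, so a delay is not settled.

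For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts of genes were 216, 0, 1216 and 12 at 5 days, 2, 3 and 6 weeks, reached by 1, 10, 1 and 1 of the 10 splits, with 1, 133, 4 and 0 genes as the highest other. For 6 weeks against 5 days, 5699 genes in BL10 and 6171 in mdx were reached by 1 of 10 splits each, with 1 and 0 as the highest other. The counts of lists, 9, 6, 16 and 11, were reached by 4, 9, 4 and 1 of the 10 splits, with 12, 16, 18 and 9 as the highest other. At 5 days, 2 weeks and 3 weeks other splits called more lists than the labels did, so the number of lists called with the preset correlation says little there.

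The arrays labelled mdx at 2 weeks replicate 1 and mdx at 3 weeks replicate 1 correlated at 0.988 across genes, with a standard deviation of differences of 0.272. The highest correlation of any other 2 arrays of these ages was 0.978, between mdx at 2 weeks replicate 2 and BL10 at 3 weeks replicate 2. Their neutrophil and granulocyte marker means were 8.54 and 8.62, the highest of the 24 arrays. Genes are not independent replicates, and no explanation was tested.

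Xist read 11.65 in BL10 at 5 days replicate 1, where Eif2s3y was at the floor of 4, and 8.0 in mdx at 2 weeks replicate 2. The next highest value was 6.58, in BL10 at 5 days replicate 2.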
